A study of Mus musculus with 8 samples.

How the data were processed

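Gene expression was measured in 4 lines of A20, a mouse B lymphoma cell line of mature B cell type, with 2 arrays per line and 8 arrays in all. The lines were untransfected cells, a stable transfectant carrying membrane IgM, and 2 stable transfectants carrying IgE, clones 18 and 41. Per the labels' protocols, cells grew in RPMI medium with 10% serum and 50 µM beta-mercaptoethanol at 500000 cells/mL, and 1 µg of total RNA was used for each array. Groups and replicate numbers came from the sample titles and characteristics.

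Each sample was hybridised with a single dye, Cy3, to an Agilent mouse array of design 028005. Per the file headers, the slide was read with Agilent Feature Extraction 10.7.3.1 under its 1-colour gene expression protocol, and the probes were placed on the mouse build mm9. Per the file headers, the processed intensity of a spot had its background subtracted and was detrended by the scanner software, and it was not normalized between arrays. The deposited files also hold the mean and median pixel intensity of each spot, the intensity of its local background, and flags for spots well above background, saturated or outlying. A value table of the whole series was also deposited by the authors, in log2 units. Its columns had medians of 5.9 to 5.92 and ranked the probes exactly as the median pixel intensity did (Spearman 1 on each array). Quantile normalization without background subtraction was inferred from these values, and no label or header states it. All 8 arrays lay on 1 slide with 1 scan time, so neither could be tested as a batch. Each line filled a slide column of its own and each replicate number a slide row, so slide column and line cannot be told apart.

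The log2 processed intensity of each array was scaled by subtracting the 75th percentile of its probes. That percentile ran from 474 to 664 intensity units, a ratio of 1.4 between the brightest and the dimmest array. Control spots and spots flagged as non-uniform or as population outliers were left out, and repeated spots of a probe were averaged. A probe was kept if it was well above background on both arrays of at least 1 line, which left 29140 of 55681 probes. Each gene name was represented by its probe with the highest mean signal, which gave 19973 genes, 17358 of them well above background on all 8 arrays. Of the genes tested, 21 had a missing value. Gene names are those of the array design. An accession of 12379 tested genes was found in a reference table of assembly GRCm38.p6, and 1332 of these now carry another symbol, given in parentheses where a gene is named. Coordinates are those of the array files on mm9.

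A model with 1 mean per line was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, so that all lines shared 1 estimate of the spread (4 residual and 2.66 prior degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. The main comparison set the mean of the 2 IgE clones against the mean of the 2 control lines. Each clone was also set against each control, IgM cells against untransfected cells, and clone 41 against clone 18. Heavy chain probes were tested one by one in a fit of all 29140 probes. A gene that was not well above background, or was saturated, on every array of a line or side has only a bound there. Its fold is then printed as "at least", computed from the mean of the brighter side and, on the dimmer side, the higher of the probe's own signal and the lowest signal among probes well above background on that array (log2 -4.9 to -4.63). The number of arrays limits the precision of every value.

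A set of 20 gene lists was fixed in advance and tested with camera at a preset correlation of 0.01, in lists with at least 5 genes tested. The test was repeated with the correlation estimated for each list. Counts of list members were taken over all genes tested and again adjusted over the list alone. Genes were named by a rule fixed in advance. In the main comparison it took, among genes with a symbol that changed in both clones against both controls and were well above background on all arrays, the 12 rising and 12 falling with the largest smallest change over the 4 pairwise comparisons, plus up to 6 per direction by the largest bound. It took the 8 largest per direction and up to 4 by bound in the 2 other contrasts, the 3 largest per direction in each pairwise comparison, up to 4 called members of each list (2 in the other contrasts), all heavy chain probes, and 11 fixed genes whatever their values. Where the text gives fewer genes than the rule allows, they are examples from it.

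The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter or a stricter filter on dim probes, the authors' deposited log2 table, every probe as its own feature, outlier spots kept, trend and robust priors, adjusted p alone, each array left out in turn, the replicate number as a block, a 2-group fit with or without the line as a random block, and fits of the 4 arrays compared. The procedure was tested on simulated data of 19973 genes for the main comparison. It recovered 0% of 50 genes changed 1.5-fold, 66% at 2.5-fold, 96% at 4-fold and 100% at 8-fold, with 5 false calls. A change of 1.5-fold lies under the 2-fold threshold of a call. The simulated values were independent between genes, with the same spread in every line and no other difference between lines. The 5 false calls therefore do not cover differences between lines, correlated genes or the wider spread of the untransfected arrays. Figures were drawn with matplotlib 3.10.9.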

Results

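The series compared mouse A20 B lymphoma cells that carry transfected IgE with untransfected cells and with cells that carry transfected membrane IgM. A20 is a line of mature B cells that makes an IgG heavy chain of its own. Each of the 4 lines (untransfected, IgM, IgE clone 18 and IgE clone 41) was measured on 2 one-colour arrays. Between 49.7% and 58.9% of probe spots were well above background on an array. The 2 untransfected arrays differed more from each other (SD of the log2 difference 0.65 over 17358 genes) than the 2 arrays of the IgM line (0.36), clone 18 (0.32) or clone 41 (0.37). The first principal component held 48.9% of the variance and placed the 4 IgE arrays at 28.8 to 47.1 and the 4 control arrays at -43.2 to -30.2. The labels do not say that the arrays of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values.

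Among the heavy chain probes, which bear on the manipulated genes, the mu probe was highest in IgM cells and the epsilon probe did not separate the IgE lines from the others. The array held 13 probes in the heavy chain constant region (mm9 chromosome 12, 114509504 to 114659689), 9 of them named for a constant gene. The epsilon probe (Ighe, starting at 114509504) read -0.76 ± 0.64 in untransfected cells, 0.56 ± 0.66 in IgM cells, 0.42 ± 0.09 in clone 18 and 0.13 ± 0.38 in clone 41 (log2 signal over the array's 75th percentile, SD, n = 2). Its difference between IgE and control lines was 0.38 ± 0.29 (SE, limma adjusted p = 0.408). The mu probe was well above background in every line, and both IgM arrays (4.88 and 4.64) exceeded the other 6 (3.65 to 4.29). It was lower in clone 18 than in IgM cells (-1.04 ± 0.19, adjusted p = 0.0188), differed by -0.83 ± 0.19 in clone 41 (adjusted p = 0.046), short of 2-fold, and by 0.63 ± 0.19 between IgM and untransfected cells (adjusted p = 0.2). Between IgE and control lines the mu probe differed by -0.62 ± 0.13 (adjusted p = 0.0249), short of 2-fold. The files do not state whether either probe matches the transfected sequences, so they check the labels in part at most.

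Among the other named constant probes, those for gamma 2a were near or at saturation in all lines. A probe described as gamma 1 (starting at 114567263) was higher in IgM cells (2.7 and 2.97 on the 2 arrays) than in untransfected cells (adjusted p = 0.0114), where replicate 1 read -3.26 and replicate 2 was not well above background, so no fold is given. The fit also called it lower in the IgE than in the control lines (adjusted p = 0.00586). No IgE array kept was well above background, and the spot of clone 41 replicate 2, left out as non-uniform, had a signal of 3390 against 4260 and 4560 on the IgM arrays, so no size is given for that difference. A second gamma 1 probe, starting at 114568594, differed by 0.19 ± 0.37 between IgM and untransfected cells (adjusted p = 0.888). The probe at 114654277, described as a delta chain constant region and named Ighv14-2 by the array design, was 2.25-fold higher in the IgE lines in the pooled contrast (1.17 ± 0.29, adjusted p = 0.0385). It was not called in either clone against either control (adjusted p 0.116 to 0.191), and the untransfected arrays read -2.63 and -1.31. With normexp background correction, 1 of the 9 named probes was called between IgE and control lines in place of 2.

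The IgE lines differed from the control lines in 1795 of 19973 genes, 679 higher and 1116 lower. Slc16a3, which encodes the lactate exporter MCT4 (mm9 chromosome 11, 120820023), rose 131-fold, from -2.48 ± 0.85 in the control lines to 4.56 ± 0.60 in the IgE lines (log2 signal, SD, n = 4 arrays each). Rgs13, a regulator of G protein signalling (chromosome 1, 145985824), rose 75.5-fold, and the T-type calcium channel gene Cacna1h (chromosome 17, 25511235) rose 56.7-fold. Gabrr1, a GABA receptor subunit, fell by 6.51 ± 0.21 on the log2 scale, the ubiquitin ligase gene Cblc fell by 6.51 ± 0.17, and Ptpn7, a leukocyte tyrosine phosphatase, fell by 6.15 ± 0.15 (SE). The adjusted p of these 6 genes ran from 4.13e-06 for Ptpn7 to 0.000852 for Rgs13.

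In both IgE clones against both controls, 585 genes changed the same way, 209 higher and 376 lower. Of those with a symbol and measured on all 8 arrays, 77 rose and 149 fell. Besides the genes above, Ng23 (Sapcd1) rose 19.7-fold, Basp1 15.5-fold, the cell cycle gene Spdya 14.3-fold, Litaf 13.2-fold, Cacng7 12.8-fold and AI844869 11.4-fold. Ppfia4 rose 10.5-fold, although its other probe had the opposite sign, the linker histone gene Hist1h1a (H1f1) rose 9.04-fold and Creg1 8.39-fold. Among genes not well above background in any control array, Decr1, a mitochondrial enzyme of fatty acid oxidation, was at least 248-fold higher, Npc1l1, a cholesterol uptake protein, at least 129-fold, the ketone body enzyme gene Bdh1 at least 106-fold, Armcx2 at least 91.4-fold, and the p53 target Phlda3 at least 50.9-fold. Among falling genes, Anxa10 changed 56.2-fold, the protease inhibitor gene Slpi 47.7-fold, Slit1 44.9-fold, the lymphocyte adaptor gene Sash3 42.5-fold, Casp4 24.9-fold, Hnrpll (Hnrnpll) 20.5-fold, Tmem52 17.6-fold and Capn3 16-fold. The integrin gene Itga6 fell 26.4-fold by the probe used and was not called by its other probe. Ccdc113 was at least 113-fold lower, the TNF family ligand Cd70 at least 78.8-fold, Nedd9 at least 78.3-fold and Wnt6 at least 71.7-fold. The count of 585 fell to 280 and 342 without clone 41 replicate 1 or 2, and to 315 and 323 without clone 18 replicate 1 or 2.

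**Figure D1:**
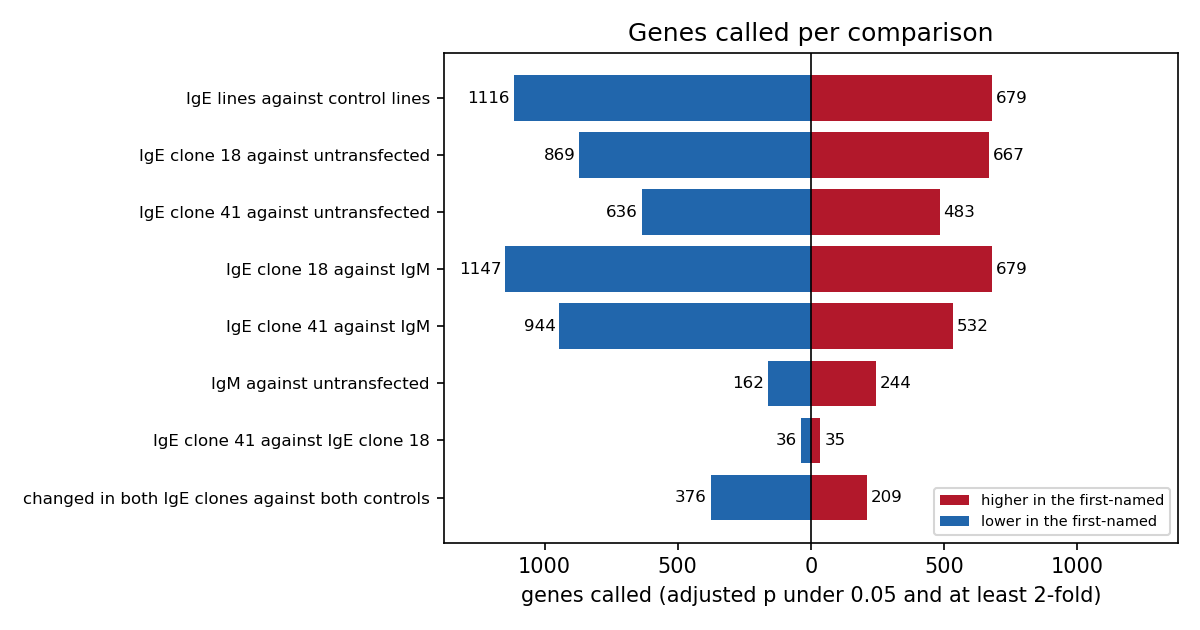
Number of genes called in each comparison (x axis, adjusted p under 0.05 and at least 2-fold), higher in the first-named lines to the right and lower to the left. The IgE lines had 679 genes higher and 1116 lower than the control lines, and the 2 IgE clones differed from each other in 35 and 36 genes.

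Genes of B cell receptor signalling and B cell identity went both ways. Of 33 receptor and co-receptor genes tested, 6 fell and 1 rose, with the same counts adjusted over the list alone, and the list did not pass the set test (adjusted p = 0.153), except without untransfected replicate 2 (adjusted p = 0.0262). The kinase gene Fyn fell by 2.30 ± 0.24 on the log2 scale and the complement receptor gene Cr2 by 1.67 ± 0.22, although in clone 41 against untransfected cells Fyn differed by -1.16 (adjusted p = 0.1). Cd72 was lower by 1.24 ± 0.13 in the pooled contrast, which rested on IgM cells: it differed by 0.01 and -0.55 from untransfected cells in clones 18 and 41 (adjusted p 0.98 and 0.139), and the call ended in 2-group fits without and with the line as a random block (adjusted p 0.135 and 0.141). Cd79a, a signalling chain of the B cell receptor, differed by -0.84 ± 0.14 (adjusted p = 0.00842), a change of 1.79-fold that did not reach the fold threshold, and Cd79b, saturated on 3 arrays, by 0.26 ± 0.14. Of 30 mature and germinal centre B cell genes, 7 fell and 2 rose (list adjusted p = 0.526, the same counts over the list alone). The chemokine receptor gene Cxcr5 fell 12-fold and the transcription factor gene Ebf1 4.8-fold, and neither passed in clone 41 against untransfected cells (adjusted p 0.0748 and 0.0955). Pax5 differed by 0.64 ± 0.21 (adjusted p = 0.0744) and Bcl6, saturated on 2 arrays, by 0.11 ± 0.12. The low-affinity IgE receptor gene Fcer2a fell 3.53-fold (adjusted p = 0.029) and lost its call when an IgM or IgE array was left out (adjusted p 0.0506 to 0.101). Against IgM cells it differed by -0.54 in clone 18 and -0.86 in clone 41 (adjusted p 0.61 and 0.441). Btla was 3.45-fold higher in the pooled contrast, which rested on untransfected cells (3.47 in clone 18 and 4 in clone 41). It differed from IgM cells by -0.43 and 0.11 (adjusted p 0.486 and 0.891), and the call ended in the 2-group fits (adjusted p 0.254 and 0.262).

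Of 19 plasma cell genes tested, 2 fell and 0 rose, also over the list alone, and 10 had an unadjusted p under 0.05 (list adjusted p = 0.225). They were Irf4, a transcription factor of activated B cells and plasma cells, which fell 6.94-fold (-2.80 ± 0.30, adjusted p = 0.00163), and Prg2, at least 43.4-fold lower. The change of Irf4 against IgM cells alone did not pass in clone 41 (-1.57 ± 0.43, adjusted p = 0.0734). Prdm1 differed by 0.47 ± 0.58, Xbp1 by -0.45 ± 0.16 and Sdc1 by -0.94 ± 0.27 (adjusted p 0.609, 0.0921 and 0.0554). Sdc1 passed when untransfected replicate 2 was left out (-1.24, adjusted p = 0.00256). Among 25 pro-apoptotic genes, Bcl2l11, which encodes the BH3-only protein BIM, rose 4.52-fold (2.18 ± 0.30, adjusted p = 0.00429, not called in clone 41 against IgM cells, adjusted p = 0.0575), and 1 further gene rose and 1 fell (list adjusted p = 0.488). Of 16 anti-apoptotic genes, 2 rose and 0 fell, Bcl2a1d by 16.3-fold and Bcl2a1c by at least 1.83-fold (list adjusted p = 0.526). The counts of both apoptosis lists were the same over the list alone. Bcl2a1d lost its call when clone 18 replicate 1 or 2, clone 41 replicate 1 or IgM replicate 2 was left out (adjusted p 0.0512 to 0.0683) and among the 4 pairs passed in clone 41 against untransfected cells alone, and Hax1 differed by 0.16 ± 0.13.

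**Figure D2:**
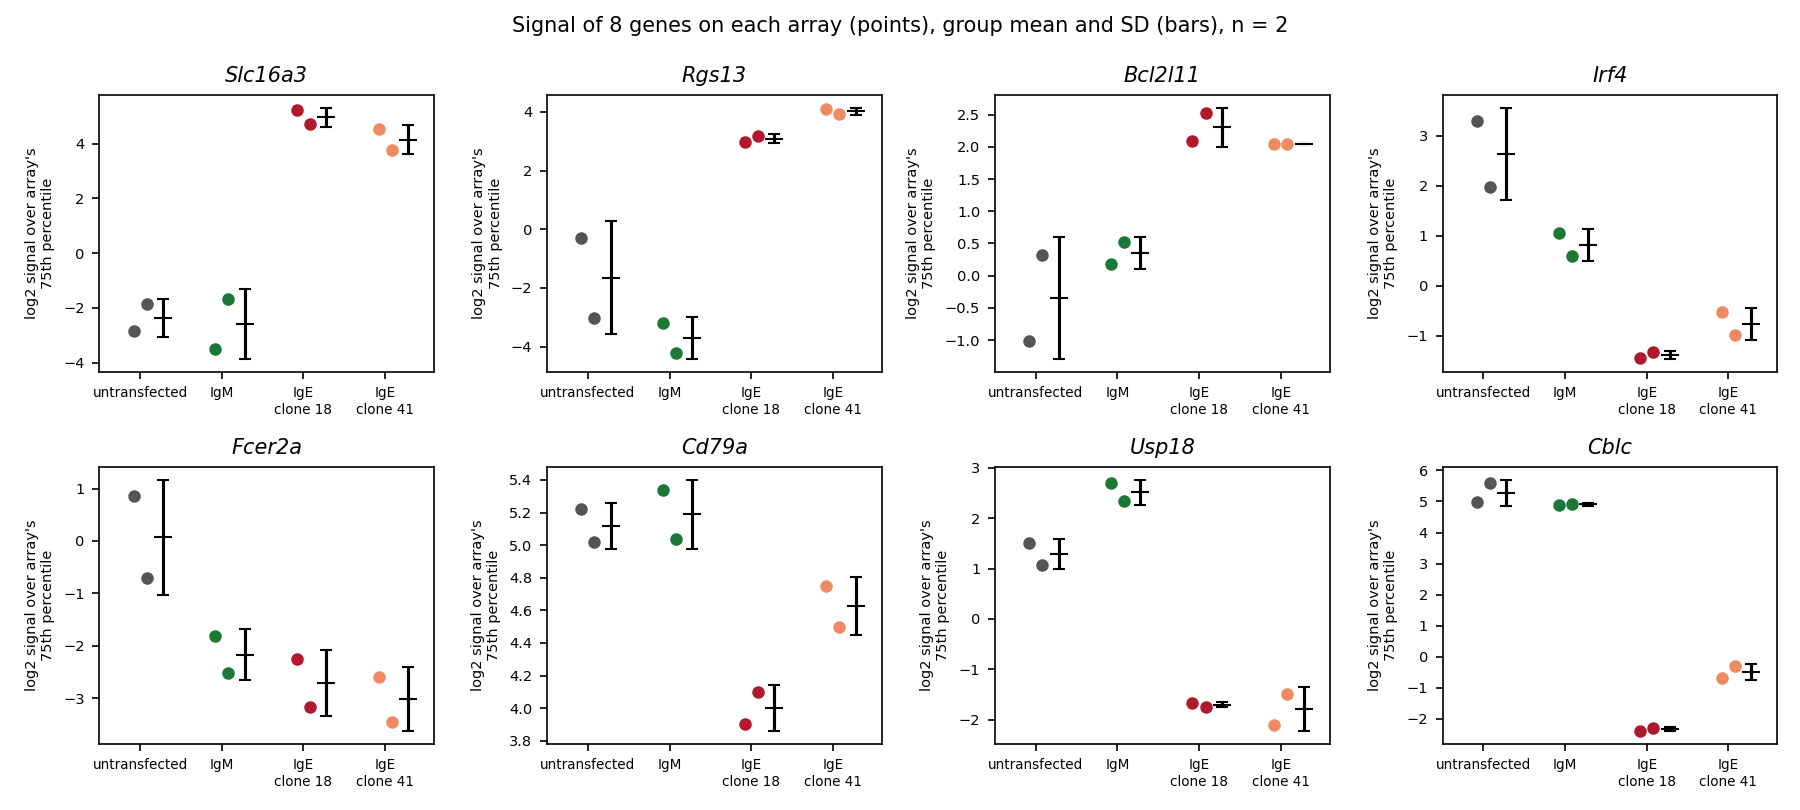
Signal of 8 genes (y axis, log2 over the array's 75th percentile) in each line (x axis), with points for the 2 arrays and bars for the mean and SD. Slc16a3 lay at 4.56 in the mean of the IgE lines and at -2.48 in that of the control lines, and Cblc at -1.41 and 5.09.

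As groups, glycolysis and hypoxia genes shifted up, interferon response genes shifted down and cholesterol synthesis genes shifted up at the preset correlation, and none of the 3 calls held with an estimated one. Of 27 glycolysis and hypoxia genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.64 (adjusted p = 1.05e-05, and adjusted p = 0.599 with an estimated correlation). Besides Slc16a3, the stress-induced mTOR inhibitor gene Ddit4 rose 5.97-fold and the enolase gene Eno2 5.91-fold, whereas Ndrg1 fell 6.07-fold. In clone 41 against untransfected cells Ddit4 and Eno2 did not pass (adjusted p 0.0583 and 0.118), and neither did Ndrg1 in clone 18 against IgM cells (adjusted p = 0.303). Hk1, Gpi1, Aldoa, Gapdh, Pgk1, Pgam1, Eno1 and Ldha were saturated on 4 to 8 arrays, with values of 0.21 to 0.52. The 75th percentile subtracted was lower on the IgE arrays (474 to 524) than on the control arrays (584 to 664). Scaling alone can therefore raise a saturated gene in the IgE lines, and these genes count toward the upward shift of the list. Of 27 type I interferon response genes, 11 fell and 1 rose, also over the list alone, with a median of -0.55 (adjusted p = 0.000358, and adjusted p = 0.599 with an estimated correlation). The ISG15 protease gene Usp18 fell 12.5-fold and Xaf1 6.94-fold. Mx2 and Rsad2, not called in clone 41 against untransfected cells (adjusted p 0.0603 and 0.0596) and not well above background in any IgE array, were at least 1.45-fold and 1.4-fold lower and lost their calls with normexp background correction (log2 -0.20 and -0.23). Mx2 was not called in clone 18 against untransfected cells either (-1.44, adjusted p = 0.137), so among the 4 pairs it passed against IgM cells alone. Of 30 cholesterol synthesis genes, none was called over all genes or over the list alone, and 7 had an unadjusted p under 0.05. Their median was 0.68 (adjusted p = 0.0123, and adjusted p = 0.832 with an estimated correlation). The cholesterol list lost its call without untransfected replicate 2 (median 0.28, adjusted p = 0.0706), without clone 41 replicate 1 (0.6, adjusted p = 0.0624) and in a 2-group fit with the line as a random block (adjusted p = 0.231), and its median differed by 1.53 between the 2 untransfected arrays.

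**Figure D3:**
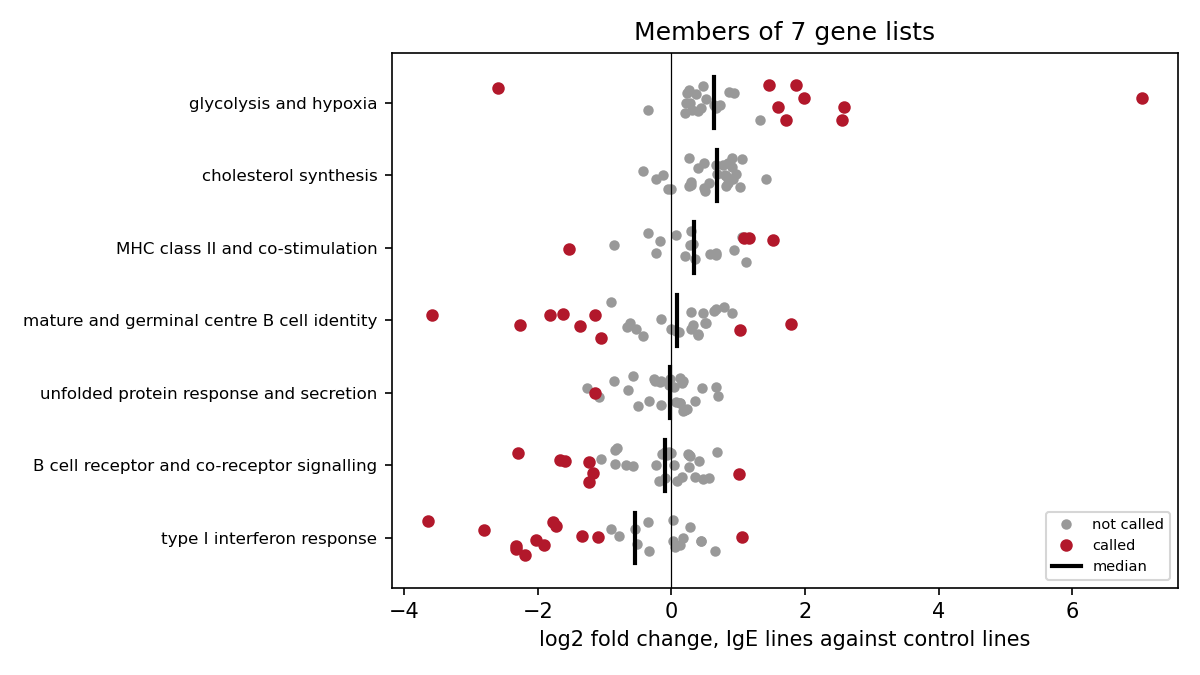
Fitted log2 change between IgE and control lines (x axis) of the tested members of 7 gene lists (y axis), with a point per gene, called genes in red, and the list median as a bar. The medians were 0.64 for glycolysis and hypoxia and -0.55 for the type I interferon response.

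The remaining lists did not pass the set test in this comparison, apart from NF-kB targets without untransfected replicate 2 (adjusted p = 0.0469). Of 30 adhesion and chemotaxis receptor genes, 3 rose and 6 fell (adjusted p = 0.129), among them Rgs13, Rgs16 (at least 43.6-fold lower in the pooled contrast, not called in clone 41 against untransfected cells, -3.36, adjusted p = 0.0606), Cd97 (Adgre5, 7.44-fold lower) and the sphingosine phosphate receptor gene S1pr1 (4.52-fold lower in the pooled contrast, not called in clone 41 against untransfected or IgM cells, adjusted p 0.118 and 0.055). Of 20 genes of MHC class II and co-stimulation, 3 rose and 1 fell (4 and 1 over the list alone, adjusted p = 0.114). B2m, which encodes the light chain of MHC class I and was saturated on 2 arrays, was at least 2.88-fold lower. Cd86 was 2.87-fold higher in the pooled contrast, which rested on IgM cells (3.68 in clone 18 and 3.59 in clone 41). Against untransfected cells it differed by -0.56 and -0.64 (adjusted p 0.141 and 0.125), and the call ended in the 2-group fits (adjusted p 0.361 and 0.369). Of 20 NF-kB targets, 3 fell and 0 rose (adjusted p = 0.114). Il10 was 2.82-fold lower and lost that call without clone 18 replicate 1 or 2 or clone 41 replicate 1. Among the 4 pairs Il10 passed in clone 41 against IgM cells alone, and Traf1 in clone 18 against untransfected cells alone. Ccl5 differed from IgM cells by -0.33 in clone 18 and 0.62 in clone 41 (adjusted p 0.649 and 0.4). The early activation marker Cd69 fell 8.6-fold and Klf4 rose 2.69-fold among 25 immediate early genes, of which 2 rose and 2 fell (adjusted p = 0.777, with a median of 0.19 against a mean of -0.03). Of 36 cell cycle genes, 1 rose, the CDK inhibitor gene Cdkn2c by 3.43-fold, and 0 fell (adjusted p = 0.526). In clone 41 against IgM cells Cdkn2c differed by 0.96, short of 2-fold. Among 42 actin genes, 1 rose and 2 fell, including Cotl1 at 2.92-fold lower, not called in clone 41 against IgM cells (adjusted p = 0.0507; list adjusted p = 0.659). Among 29 genes of the unfolded protein response and secretion, 1 fell, Edem1 by 2.22-fold (adjusted p = 0.688), and Edem1 was under 2-fold without IgM replicate 1 (log2 -0.99) and not called in either clone against IgM cells (adjusted p 0.0954 and 0.127). Of 17 p53 targets, Phlda3 rose and Rrm2b fell 3.12-fold (adjusted p = 0.825), and Rrm2b did not pass in clone 41 against untransfected cells (adjusted p = 0.0763). Except where given, these counts were the same over the list alone.

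Markers of other cell types moved in both directions. Of 11 T cell markers, 3 fell (adjusted p = 0.114), with Cd5 3.29-fold lower. Of 10 myeloid markers, 3 rose and 1 fell (4 and 1 over the list alone, adjusted p = 0.114), with Cd68 3.2-fold and Fcgr3 2.25-fold higher and the macrophage marker Emr1 (Adgre1) 21.2-fold lower. In clone 41 against untransfected cells Cd5 (adjusted p = 0.0806) and Cd68 (adjusted p = 0.0521) did not pass. Fcgr3 was short of 2-fold in clone 41 against both controls (0.96 against IgM cells, and 1 after rounding against untransfected cells). Of 8 stromal and erythroid markers, 3 rose (3 higher and 1 lower over the list alone, adjusted p = 0.659), among them the erythropoietin receptor gene Epor at 5.18-fold. The haemoglobin gene Hbb-b1 (Hbb-bt) was 3.67-fold higher in the pooled contrast, which rested on IgM cells (4.87 in clone 18 and 2.71 in clone 41). Against untransfected cells it differed by 1.04 and -1.12 (adjusted p 0.155 and 0.164), and the call ended in the 2-group fits (adjusted p 0.286 and 0.294). Of 4 mast cell, basophil and NK cell markers measured, too few for a set test, Klrb1c was at least 8.19-fold lower.

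Each clone was also set against each control line, the pairs that the design names. Against untransfected cells 1536 genes changed in clone 18 (667 higher, 869 lower) and 1119 in clone 41 (483 higher, 636 lower). Against IgM cells the counts were 1826 (679 higher, 1147 lower) and 1476 (532 higher, 944 lower). Among genes with a symbol that were well above background on all 8 arrays, Slc16a3 was among the 3 largest increases in all 4 pairs. Its rise ran from 91.4-fold in clone 41 against untransfected cells to 189-fold in clone 18 against IgM cells. Rgs13 was 213-fold and Emp3, a membrane protein gene, 94.4-fold higher in clone 41 than in IgM cells. Zfpm1, the GATA cofactor FOG1, was 110-fold lower in clone 41 than in untransfected cells, and Sytl3 157-fold and the fructose transporter gene Slc2a5 115-fold lower in clone 41 than in IgM cells. Erdr1, saturated on 6 arrays, was at least 208-fold lower in clone 18 than in untransfected cells. Cd79a was lower in clone 18 than in untransfected (-1.12 ± 0.20, adjusted p = 0.0175) and IgM cells (-1.19 ± 0.20, adjusted p = 0.012). In clone 41 it differed by -0.49 and -0.56 (adjusted p 0.2 and 0.14), and it was not called between the clones.

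The changes of the clones overlapped when each was compared with a different control, so that the log2 changes shared no array. The calls were not separate, since the spread of each gene was estimated from all arrays. Of 667 genes higher in clone 18 than in untransfected cells and 532 higher in clone 41 than in IgM cells, 250 were shared, against 17.8 for independent lists, and of 869 and 944 lower genes 460 were shared, against 41.1. With the controls exchanged, 253 higher and 428 lower genes were shared, against 16.4 and 36.5. A gene with a small estimated spread is more readily called in both lists. The values for independent lists are therefore not the overlap of unrelated changes, and the excess over them was not tested. Across genes, which are not independent replicates, the log2 changes, which do not use the spread, correlated at 0.59 and 0.61. Against untransfected cells the count moved to 2539 for clone 18 and 2121 for clone 41 without untransfected replicate 1. It moved to 580 and 676 for clone 18 without its own replicate 1 or 2, and to 469 and 570 for clone 41. Against IgM cells it moved to 795 and 877 for clone 18 and to 720 and 818 for clone 41 without replicate 1 or 2 of that clone. Without IgM replicate 1 or 2 it moved to 1025 and 1186 for clone 18 and to 813 and 954 for clone 41.

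IgM cells, the control for transfection with another membrane immunoglobulin, differed from untransfected cells in 406 genes, 244 higher and 162 lower. The kallikrein gene Klk8 rose 49.1-fold (5.62 ± 0.20, adjusted p = 0.000123), the dystrophin gene Dmd 25-fold, the nuclear receptor gene Rorb 24.1-fold and Btla, an inhibitory lymphocyte receptor, 14.9-fold. Ifitm2 rose 14.1-fold and Ifi27l1 (Ifi27) 12.6-fold, and the T cell receptor component Cd3g was at least 13.9-fold higher. Nlrp4f fell 38.8-fold, Cd70 33.2-fold, the G protein-coupled receptor gene Gpr132 32.7-fold, Emp3 26.9-fold, Timd2 19.7-fold and the co-stimulatory ligand Cd86 18.9-fold. Usp54 fell 38.8-fold by the probe used and was not called by its other probe. Dlg5 was at least 54-fold and Defb19 at least 49.6-fold lower. Hbb-b1 and Hbb-b2 fell 14.2-fold and 14-fold. Some of these calls ended when single arrays were left out: Ifitm2 without either IgM array (adjusted p 0.0647 to 0.0695), Ifi27l1 without either IgM or clone 18 array or untransfected replicate 1 (0.0815 to 0.188), Nlrp4f without IgM replicate 2 or either untransfected or clone 41 array (0.0569 to 0.103), Cd70 without any IgM or IgE array (0.0527 to 0.1) and Timd2 without IgM replicate 2 or either clone 18 array (0.0549 to 0.0688). All 5 also ended with no filter on dim probes (adjusted p 0.0626 to 0.151), and Ifi27l1 with quantile normalization (0.0695) and the authors' values (0.0894). Among genes well above background on all 8 arrays the balance turned, with 84 higher and 104 lower of 188. With the authors' values 161 genes passed, 91 higher and 70 lower. With no filter on dim probes 229 passed. The count of 406 moved to 882 and 648 without untransfected replicate 1 or 2, to 260 without IgM replicate 1 and to 248 without either clone 18 array, and it was 100 in a fit of the 4 arrays alone.

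Among the gene lists, those of the unfolded protein response and of MHC class II had lower medians in IgM than in untransfected cells. The unfolded protein response list had a median of -0.66 over 29 genes, of which 0 were called and 13 had an unadjusted p under 0.05 (list adjusted p = 2.72e-08, and adjusted p = 0.749 with an estimated correlation). The MHC class II list had a median of -0.53 over 20 genes, with 1 lower, Cd86 (3 over the list alone, list adjusted p = 1.48e-05, and adjusted p = 0.318 with an estimated correlation). NF-kB targets (-0.27, adjusted p = 0.00766, 2 of 20 lower), mature B cell genes (0.35, adjusted p = 0.0337, 1 of 30 higher), stromal and erythroid markers (-0.72, adjusted p = 0.0337, 2 of 8 lower, 3 over the list alone) and glycolysis genes (-0.21, adjusted p = 0.0376, 1 of 27 lower, 2 over the list alone) also passed at the preset correlation. With an estimated correlation their adjusted p was 0.318, 0.749, 0.318 and 0.749. Each of these 4 lists lost its call without an array: NF-kB targets without untransfected replicate 1 (adjusted p = 0.0875), mature B cell genes without untransfected replicate 2 (0.777) or IgM replicate 1 (0.188), stromal and erythroid markers without IgM replicate 1 (0.0589), and glycolysis genes without untransfected replicate 1 (0.0575) or 2 (0.0594) or IgM replicate 1 (0.188). Ebi3 fell 5.39-fold, Ccl5 5.14-fold and Pfkp 2.72-fold, although the other Pfkp probe was not called, and Cd72 rose 3.83-fold. The calls ended for Ebi3 without either IgM or clone 18 array (adjusted p 0.0844 to 0.118), for Ccl5 without these or untransfected replicate 2 (0.0733 to 0.138) and for Pfkp without any single array (0.0548 to 0.159). With quantile normalization B cell receptor (adjusted p = 0.024) and cell cycle genes (0.00365) passed, and glycolysis genes (0.187) did not. Lists that passed when an untransfected array was left out were B cell receptor (adjusted p = 0.00188) and cell cycle genes (0.000142) without replicate 1, actin genes (0.0138) and T cell markers (0.0154) without replicate 2, and cholesterol synthesis genes without either, in opposite directions (medians 0.67 and -0.84).

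The IgE clones differed from each other in 71 genes, 35 higher in clone 41 and 36 lower. Erdr1 was at least 269-fold higher in clone 41, and Cd99, a surface protein gene, was 82.5-fold higher (6.37 ± 0.26, adjusted p = 0.000158). The homeobox gene Rhox5 was 6.63-fold, Dlg5 5.57-fold, Il2rg, which encodes the common cytokine receptor chain, 4.36-fold and the lymphocyte receptor gene Cd6 4.17-fold higher. Ppp2r2c was at least 45.9-fold and Gstk1 at least 13.2-fold lower in clone 41, the homeobox gene Rhox2h 47.5-fold, Wdr96 (Cfap43) 9.88-fold and the signal transducer gene Stat5b 3.16-fold lower. Zfp941 was 12.4-fold lower by the probe used and was not called by its other probe. Calls ended for Rhox2h (adjusted p 0.101 to 0.194) and Stat5b (0.0993 to 0.117) without any IgE array, for Il2rg without any IgM or IgE array (0.0814 to 0.297), for Rhox5 (0.0521 to 0.111) and Wdr96 (0.0614 to 0.124) without either clone 18 array or clone 41 replicate 1, for Dlg5 without clone 18 replicate 1 or either clone 41 array (0.0554 to 0.0613), and for Cd6 without clone 18 replicate 2 or either clone 41 array (0.0895 to 0.122). The count was 32 and 30 without clone 18 replicate 1 or 2 and 38 and 37 without clone 41 replicate 1 or 2.

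Glycolysis and cholesterol synthesis genes had lower medians in clone 41 than in clone 18 at the preset correlation. The median of 27 glycolysis genes was -0.37 (adjusted p = 0.00047, and adjusted p = 0.314 with an estimated correlation) and that of 30 cholesterol synthesis genes -0.58 (adjusted p = 0.000508, and adjusted p = 0.565 with an estimated correlation), with 0 members called in either (0 higher and 1 lower glycolysis gene over the list alone). Without clone 41 replicate 2 their adjusted p was 0.0607 and 0.0763. Stromal and erythroid markers (-0.37, adjusted p = 0.00589), immediate early genes (0.31, adjusted p = 0.0071), MHC class II genes (0.09, adjusted p = 0.02) and, at adjusted p = 0.0332 each, plasma cell (0.16), unfolded protein response (0.13) and adhesion genes (0.04, against a mean of 0.38, with 15 of 30 genes positive) also passed, as did p53 targets (0.2, adjusted p = 0.048). With an estimated correlation the unfolded protein response list had an adjusted p of 0.766 and the other 6 an adjusted p of 0.314. Immediate early genes lost the call without clone 41 replicate 1 (adjusted p = 0.0912), and MHC class II (0.0639), adhesion (0.226), plasma cell (0.33), p53 (0.0832) and unfolded protein response genes (0.0832) lost it without clone 41 replicate 2. Plasma cell (0.143) and p53 genes (0.355) also lost it without clone 18 replicate 1, adhesion genes without clone 18 replicate 2 (0.112), and p53 (0.132) and unfolded protein response genes (0.0836) without clone 41 replicate 1. Unfolded protein response genes also lost it without clone 18 replicate 1 (0.938) and, like p53 genes (0.0736), with quantile normalization (0.0603). T cell markers passed without clone 18 replicate 1 (0.0328) or clone 41 replicate 1 (0.017), cell cycle genes without clone 18 replicate 2 (0.0416), and mature B cell genes without untransfected replicate 1 (0.0494) or 2 (0.0493).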

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

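The test of the difference between the IgE clones was chosen before the result was seen, and the grouping of its genes by the 4 pairwise comparisons afterwards. The clones differed in 71 genes, 50 of which were changed in 1 clone and not in the other against both controls, while 10 were changed in both clones against both controls and 1 went opposite ways against untransfected cells. Cblc, among the genes that fell most in both clones, fell less in clone 41 than in clone 18, with a log2 difference of 1.84 ± 0.24 (SE, limma adjusted p = 0.0459). It changed by -7.61 in clone 18 and -5.77 in clone 41 against untransfected cells, and by -7.24 and -5.40 against IgM cells, and another Cblc probe did not pass the test between the clones. Without an IgM or IgE array the call between the clones ended (adjusted p 0.103 to 0.351).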

How the results depend on the processing

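The alternatives in this part were chosen before the data were examined, except the fits without the shifted chromosome stretches and with IgM cells as the lone control, which were chosen after seeing the data. Over 3390 repeats of named-gene results, 3029 kept their direction and side of the threshold, 359 lost the call, 2 gained it and 0 reversed. Of 646 repeats of list results, 586 kept both, 44 lost and 14 gained the call and 2 reversed. The cholesterol list reversed between IgM and untransfected cells without untransfected replicate 1 (0.67, adjusted p = 6.64e-06, against -0.84 without replicate 2), and the unfolded protein response list between the clones without clone 18 replicate 1 (-0.06, against 0.34 without replicate 2). The cause of the moves below was not tested, except where fewer genes or arrays entered. Of the 1795 genes that separated IgE from control lines, 970 stayed called with normexp, 1081 with the authors' table and 1792 with outlier spots kept, and 0 reversed. That count was 1034 with normexp, 1085 with genes above background on all 8 arrays, 1117 with the authors' table, 3562 at adjusted p alone, 1456 in a plain 2-group fit, 1379 in that fit with the line as a random block (consensus correlation 0.05), 1649 outside the shifted stretches and 2170 against IgM cells alone. At a correlation of 0.05 the random block counts the arrays of a line as nearly independent, so it does not test the difference with the line as the unit. With no filter the counts were 848 and 596 for clones 18 and 41 against untransfected cells, 1178 and 944 against IgM cells, 229 for IgM against untransfected cells, 31 between the clones and 327 for both clones against both controls. With the authors' table they were 960, 667, 1117, 899, 161, 17 and 343. The all-array filter gave 1215 and 963 against IgM cells, 188 for IgM against untransfected cells (84 higher, 104 lower), 15 between the clones and 376 for both clones. Fits of 4 arrays gave 980 and 517 against untransfected cells, 100 for IgM against untransfected cells and 148 between the clones. Between the clones, normexp gave 42 (13 higher, 29 lower) and the authors' values gave 6 higher and 11 lower. With an estimated correlation 0 lists passed in each of the 3 comparisons, in place of 3, 6 and 9. Of the heavy chain probes, 1 was called with normexp. With an array left out, a lone array was assumed to vary like the other lines. The counts then ranged from 1391 to 2169 for IgE against control lines, 580 to 2539 and 469 to 2121 for clones 18 and 41 against untransfected cells, 795 to 2227 and 720 to 1916 against IgM cells, 248 to 882 for IgM against untransfected cells, 30 to 106 between the clones and 280 to 787 for both clones. Lists called ranged from 2 to 4 for IgE against control lines, 3 to 7 for IgM against untransfected cells and 2 to 10 between the clones. The replicate number is also the slide row, and with the replicate block 6 of 176 named-gene results lost the call and the counts were 1843, 1562, 1152, 1847, 1549, 411, 78 and 625, in the order of the counts above. The deviations of same-numbered arrays correlated at -0.06 to 0.35 over the pairs of lines, so a shared effect of the slide row is not excluded. Signal over background limits part of the calls, since among tested genes 62 of the higher and 146 of the lower calls between IgE and control lines were dim on a whole side.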

Other observations

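The tests chosen after the result was seen are those on the variable region, on the order of genes along chromosomes, on genes outside the heavy chain locus, on a wrong label and on the state of the cultures. In the heavy chain variable region (mm9 chromosome 12, 114659689 to 117238485), 31 of 42 probes tested were higher in IgM than in untransfected cells. The 42 include Adam6b, a lincRNA and probes of unknown target. Of the 31, 6 were also higher in both IgE clones, 2 in 1 clone and 23 in neither. The median log2 signal of the 6 shared probes was 2.37 and 2.23 on the IgM arrays, 2.01 and 2.07 in clone 18, 0.26 and 1.04 in clone 41, and -3.36 and -7.01 in untransfected cells. That of the 23 probes was 1.27 and 2.2 on the IgM arrays and between -4.81 and -2.4 on the others. Probes apart on the chromosome read alike, such as those starting at 114826538 (2.47 and 2.16 on the IgM arrays) and 115117307 (2.53 and 2.29). Whether several probes read 1 transcript was not tested, so these are not counts of separate genes. The probe of AI324046, within the constant region, was 3.96-fold higher in the IgE lines (1.99 ± 0.22, adjusted p = 0.00187).

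The number of genes that separated IgE from control lines was set against other groupings. In a 2-group fit, 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many genes, the real split itself with 1456, and the highest of the others gave 1. Splits that mix the lines add the differences between lines to the spread, and the arrays of a line may not be separate cultures, so this does not exclude a chance difference between lines. Of the 3 splits of the 4 lines into pairs, the real one called 1795 genes and the highest of the others 247, and 3 splits are too few for a share under 0.05. The effect of IgE and the separate history of each transfected line may both contribute and cannot be told apart with 2 clones and 2 control lines.

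Of the 1795 genes changed between IgE and control lines, 133 (7.41%, against 2.34% of the genes tested) lay in stretches of neighbours that shifted together, and IgM against untransfected cells also had such stretches (chromosome 10, 136 genes, -0.60, chromosome 2, 75 genes, 0.45, and chromosome 1, 44 genes, 0.46). The stretches were found from the same changes that gave the calls, so a higher share of called genes inside them is built in. Of the 133 genes, 26 lay in the stretch that holds the heavy chain locus. Between IgE and control lines the stretches outside the heavy chain locus were chromosome 1 from 159498416 to 180243520 (177 genes, median 0.61, 80.8% in that direction), chromosome 6 from 31287987 to 47703050 (0.59) and from 122527908 to 126978197 (0.48), and chromosome 19 from 39116674 to 44909954 (-0.49). The stretch in the heavy chain locus (71 genes, median -0.34) went opposite ways against the 2 controls. Its medians in clones 18 and 41 were 0.43 and 0.72 against untransfected cells, and -0.49 and -1.15 against IgM cells. Sign aside, the largest median over 40 neighbours was 1.44, a decrease in the heavy chain locus, and 0.98 elsewhere. In 1000 shuffles it was at most 0.49. These values argue against random order. The same limit defined the stretches, so this is the scan that found them and not a separate test. The shuffles also scanned fewer windows than the data, which lowers the limit. Place on the array is argued against by medians of 0.43 to 0.67 over the 4 parts of its surface. A difference in gene copy number between the lines may contribute: with genes split in 3 by signal, the lowest median shift was 0.32 (0.6 and 0.54 in the others), just past the 0.3 set for it, and 0.27 without the heavy chain locus (0.63 and 0.56), which does not decide.

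The untransfected arrays stood apart from each other, with 1745 of 17358 genes at least 2-fold apart, against 391, 141 and 329 in the IgM line, clone 18 and clone 41. A swap of either with an IgM array is argued against, since genes that set one array at least 8-fold from the IgM line left the other at a median log2 distance of 3.41 and 3.5. Distance was taken from the IgM line alone, so a wrong label of another kind is not covered. Weaker signal is argued against by an SD of 0.53 among the brightest genes (0.71 among the dimmest), where the other lines had 0.21 to 0.24. A different state of the cultures may contribute: cholesterol synthesis genes were 1.53 higher in replicate 1 in the median (percentile 100 of 10000 random lists), mature B cell genes 0.69, immediate early genes 0.52, cell cycle genes 0.49 and B cell receptor genes 0.39 higher (percentile 100 each), and unfolded protein response and interferon genes differed by -0.56 and -0.49 (percentiles 0 and 0.08). The shifts of these lists in comparisons with untransfected cells, among them the cholesterol, interferon, mature B cell and unfolded protein response calls, rest in part on these arrays. The random lists were matched on mean signal alone and ignore the correlation between members of a list. That correlation was estimated at 0.1 for immediate early genes to 0.68 for unfolded protein response genes. The percentiles can therefore overstate how unusual the shifts between the 2 arrays are.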
